A study of Homo sapiens with 6 samples.

How the data were processed

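Total RNA was isolated from stable HepG2 lines and genomic DNA was digested, per the labels' protocols. Libraries were made with a low-input kit, per the labels' protocols, and any selection of polyadenylated RNA is not given in the sources used here. The authors deposited raw counts per gene for each library, per the file headers, together with counts normalized by edgeR. The genome build was hg19 and edgeR was used, per the submitters' processing notes, with no version stated. The aligner, the counter, its use of strand and the annotation release are not given in the sources used here. The table lists 16192 genes, all protein coding, by Ensembl ID and symbol, and 18 symbols belong to more than 1 ID. The 6 columns of normalized values were not used.

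Groups and replicate numbers came from the sample titles, with 3 libraries per group. The series description calls them biological replicates without naming separate cultures or days, so p-values measure the spread between these libraries, which may be technical. Library totals ran from 31336252 to 41882303 counts. Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10, which left 11996 genes, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test with robust dispersion, the group as the only term, and Benjamini-Hochberg adjustment at 0.05 over all genes tested. CPM values use TMM-scaled library sizes. Standard errors of log2 fold changes were approximated as the fold change divided by the square root of F.

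Gene lists (34 lists, 683 entries, of which 663 were in the table) and the rule for named genes were fixed before the data were examined. The rule named SPARC, then the 10 largest rises and falls past the threshold with groups that did not overlap and a mean of at least 5 CPM in the higher group, then up to 4 members of each list with the smallest p, and 13 genes named in any case. SPARC was the only gene past the threshold, so the part of the rule for large changes was also applied to the paired fit, to genes that passed with the correction too. That extension, and ALB, were chosen after the data were examined. Some genes that the rule names are not reported here. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which left 31 lists. Counts of list members are also given adjusted over the list alone.

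Pairing by replicate number was checked by correlating deviations from the group means over tested genes. The correlations were 0.382, 0.140 and 0.348 for pairs 1 to 3, above the preset 0.1. Their mean was 0.290, but the best of 5 other matchings had 0.218, also above 0.1, so pairing stays unsettled. Values with the replicate number as a block are given beside unpaired ones. Number 3 against 1 and 2 as a block gave 4375 calls, and the 3 pairs 3451. The labels do not say what a number shares. The paired fit leaves 2 residual degrees of freedom and the unpaired fit 4.

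GC content and length came from the longest protein-coding transcript of each gene in GENCODE release 29, matched by Ensembl ID for 98.8% of tested genes. That reference is of a later genome build than the deposited table, so no coordinates are given. A natural spline of each library's deviation on GC content (6 degrees of freedom) and log2 length (4) entered the fit as an offset. The correction also removes any true change that follows GC content or length. A list of 40 squamous markers was written after the data were examined, with 10 of its genes already seen. KEGG pathways were taken from the annotation columns of the deposited table.

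The tests were checked on simulated counts with 200 changed genes. Without the block, edgeR recovered 2.44% of genes changed 1.5-fold, 30.4% at 2-fold and 88.7% at 4-fold, with 3 false calls among 77. With the block, on other counts with replicate effects, it recovered 45.1%, 67.9% and 98.4%, with 31 false calls among 167, above the 0.05 threshold. DESeq2 without the block made 45 false calls among 149. With a GC trend added between the groups the paired fit made 2357 false calls among 2498, and 7 among 132 corrected. A trend that differs within a group, as with the vector, was not simulated. Camera called the 1 moved list and 0 others, but correlated list members were not simulated.

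Alternatives planned beforehand were RLE scaling, no filter, a filter of 50 counts in 3 samples, each library left out in turn, the replicate block, DESeq2, the other set tests, and SPARC left out before scaling. Alternatives with a pseudocount applied to normalized units and were not run on counts. Further alternatives, chosen after the data were examined, were the GC and length correction with and without the block, DESeq2 with the block, number 3 against 1 and 2 as a block, both libraries numbered 3 left out, each pair left out of the corrected fit, and thinning to the smallest library.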

Results

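RNA was sequenced from HepG2, an established human hepatoma line, carrying either an empty lentiviral vector or a lentiviral construct that overexpresses SPARC, a secreted matricellular glycoprotein. Each group had 3 libraries numbered 1 to 3. Total counts over the 16192 protein-coding genes in the table were 41882303, 36250928 and 37499904 in vector replicates 1 to 3. They were 31336252, 32323592 and 36638636 in overexpression replicates 1 to 3. Each pair of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 12.8, so none was taken as 1 library deposited more than once.

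The comparison asked how SPARC overexpression changed the transcriptome, with cholesterol metabolism and PI3K-AKT signalling as the stated interests. SPARC rose from 8.22 ± 1.52 CPM in the vector libraries to 152 ± 28.9 CPM under overexpression (mean ± SD, n = 3 each). Its log2 fold change was 4.21 ± 0.22 (SE), with an adjusted p of 0.00141 in edgeR's quasi-likelihood test. Of 11996 genes tested, SPARC alone passed the threshold in this unpaired test, and 3096 genes had an unadjusted p under 0.05. DESeq2 called 1329 genes, 873 higher and 456 lower. With the replicate number as a block, edgeR called 3451 genes, 2080 higher and 1371 lower (538 and 112 at least 2-fold). After correcting this fit for transcript GC content and length, 660 genes were higher and 272 lower (20 and 81 at least 2-fold), 932 in all. With pair 1, 2 or 3 left out of that fit, 55, 404 and 3192 genes passed. Without vector replicate 3 the unpaired test called 4333 genes, 2526 higher and 1807 lower. The groups did not overlap at 4031 tested genes (33.6%), where chance gives 10%, but genes may move together. The ID of SPARC was ENSG00000113140.

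The paired log2 fold change followed GC content across genes, with a Spearman rho of 0.789 over genes, which are not independent replicates. In the tenth of genes richest in GC, 58.3% were higher and 0.169% lower in the paired fit. In the tenth poorest in GC, 0.0844% were higher and 47.9% lower. After the correction these shares were 3.12% and 3.12% at the GC-rich end, and 3.88% and 1.01% at the GC-poor end. Vector replicates 1 and 2 had rho values of -0.69 and -0.75 with GC content, vector replicate 3 had 0.212, and the 3 overexpression replicates had 0.594, 0.626 and 0.521. The paired call was kept with the correction, in the same direction, at 482 genes, 366 higher and 116 lower.

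**Figure D1:**
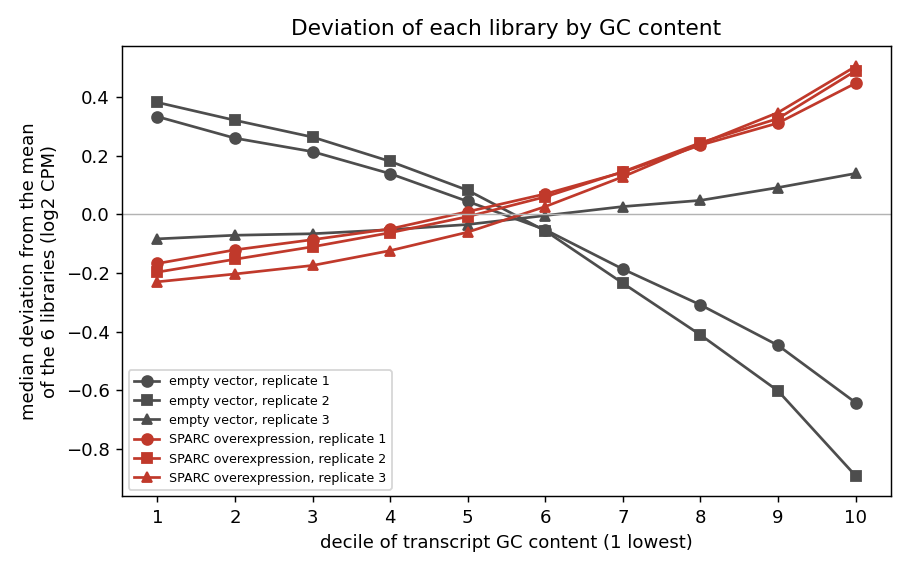
Median deviation of each library from the mean of the 6 libraries (log2 CPM, y axis) by decile of transcript GC content (x axis), 1185 genes per decile, with 1 line per library. In the GC-richest decile, vector replicates 1 and 2 lie at -0.64 and -0.89 and vector replicate 3 at 0.14, while the overexpression libraries lie between 0.45 and 0.50.

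Each gene named from here on is followed by its log2 fold change ± SE under overexpression, first unpaired, then paired, then paired with the correction (n = 3 per group). Every named gene other than SPARC had an unpaired adjusted p of 0.137 or more, so "rose" and "fell" refer to the paired tests, without and with the correction, and "both" to these 2. List counts are of genes. Leaving out 1 library moved the unpaired fold by over 1.5 times at 38 of 157 named genes, 21 without vector replicate 3 and 19 without overexpression replicate 3. In the corrected fit without pair 3, APOE (-0.64), KRT18 (-0.18), SEL1L (0.16), TRIB3 (-0.23) and LIN28B (0.22) passed against their paired direction. With an estimated correlation camera called 0 lists in each of the 3 fits, with 0, 0 and 2 at an unadjusted p under 0.05, and fry called NF-kB and acute phase inflammation in the corrected fit (adjusted p = 0.0467). Among the 10 largest falls that passed both paired tests, had groups that did not overlap and reached a mean of 5 CPM in 1 group, SRGN, which encodes the proteoglycan of secretory granules, fell the most (unpaired -6.44 ± 1.55, paired -6.28 ± 0.52, corrected -6.13 ± 0.46), on 131, 25 and 845 counts in the vector libraries and 3, 0 and 7 in the overexpression libraries. Its unpaired value was -4.29 without vector replicate 3, and its place among these 10 rests on that library, at 22.2 CPM against 3.18 and 0.718 in the other vector libraries. IGSF1 (unpaired -4.50 ± 0.65, paired -4.54 ± 0.42, corrected -4.59 ± 0.36) and MAP1B (unpaired -2.31 ± 0.30, paired -2.37 ± 0.25, corrected -2.14 ± 0.18), which encodes a microtubule-associated protein, fell as well. Further falls were DTNA (unpaired -1.78 ± 0.48, paired -1.91 ± 0.33, corrected -1.66 ± 0.28), SH2D4A (unpaired -1.57 ± 0.27, paired -1.56 ± 0.16, corrected -1.47 ± 0.12) and DUSP1 (unpaired -1.35 ± 0.21, paired -1.34 ± 0.20, corrected -1.65 ± 0.17). The other falls were GNG12 (unpaired -1.25 ± 0.30, paired -1.26 ± 0.29, corrected -0.79 ± 0.18), MAP7D2 (unpaired -1.19 ± 0.22, paired -1.18 ± 0.22, corrected -1.0 ± 0.16), LAPTM5 (unpaired -1.16 ± 0.29, paired -1.13 ± 0.19, corrected -1.18 ± 0.15) and NRCAM (unpaired -1.13 ± 0.38, paired -1.05 ± 0.23, corrected -0.74 ± 0.19). SRGN and LAPTM5 are also expressed by blood cells, and the leukocyte marker PTPRC had 50, 16 and 53 counts with the vector and 0, 1 and 13 with SPARC. The stromal marker DCN had 224, 203 and 391 counts with the vector and 3, 2 and 157 with SPARC.

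The 10 largest rises under the same limits included TSPO, the translocator protein of the outer mitochondrial membrane (unpaired 1.66 ± 0.42, paired 1.81 ± 0.34, corrected 0.92 ± 0.21). C19orf80, which encodes the secreted lipid regulator ANGPTL8, rose (unpaired 1.72 ± 0.33, paired 1.80 ± 0.27, corrected 0.94 ± 0.15), as did the renal dipeptidase gene DPEP1 (unpaired 1.77 ± 0.27, paired 1.80 ± 0.17, corrected 0.99 ± 0.09). Others were PTP4A3 (unpaired 1.61 ± 0.50, paired 1.77 ± 0.38, corrected 1.00 ± 0.27), CHPF (unpaired 1.54 ± 0.46, paired 1.75 ± 0.27, corrected 0.62 ± 0.10) and GAL3ST1 (unpaired 1.65 ± 0.38, paired 1.75 ± 0.34, corrected 0.92 ± 0.24). The remaining rises were PPP1R16A (unpaired 1.45 ± 0.53, paired 1.70 ± 0.35, corrected 0.64 ± 0.19), PKMYT1 (unpaired 1.62 ± 0.33, paired 1.68 ± 0.29, corrected 0.64 ± 0.16), LZTS3 (unpaired 1.49 ± 0.42, paired 1.64 ± 0.27, corrected 0.88 ± 0.15) and SLC39A13 (unpaired 1.39 ± 0.51, paired 1.60 ± 0.40, corrected 0.83 ± 0.24). Each of these 10 transcripts had a GC content of at least 62.5%, and the corrected values were lower than the paired ones in each.

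Of the sterol synthesis genes, EBP was among the few that passed with the correction. For sterol synthesis, 20 of 20 were tested, 7 rising and 1 falling when paired (8 and 4 adjusted over the list alone) and 2 rising and 0 falling when corrected (2 and 0 adjusted over the list alone). Sterol synthesis had camera adjusted p = 0.721 unpaired, 0.271 paired and 0.132 corrected, and 0.0108 to 0.93 over the preset-correlation fits. EBP, which encodes the sterol isomerase, rose in both (unpaired 0.57 ± 0.39, paired 0.67 ± 0.15, corrected 0.44 ± 0.10). TM7SF2, a sterol reductase gene, rose in the paired fit (unpaired 0.89 ± 0.46, paired 1.00 ± 0.19, corrected 0.24 ± 0.11) and SC5D fell in it (unpaired -0.35 ± 0.24, paired -0.40 ± 0.12, corrected 0.02 ± 0.06). PMVK (unpaired 0.61 ± 0.33, paired 0.63 ± 0.23, corrected 0.01 ± 0.19) passed neither. SQLE, the squalene epoxidase, did not pass (unpaired -0.12 ± 0.34, paired -0.16 ± 0.10, corrected -0.01 ± 0.07).

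**Figure D2:**
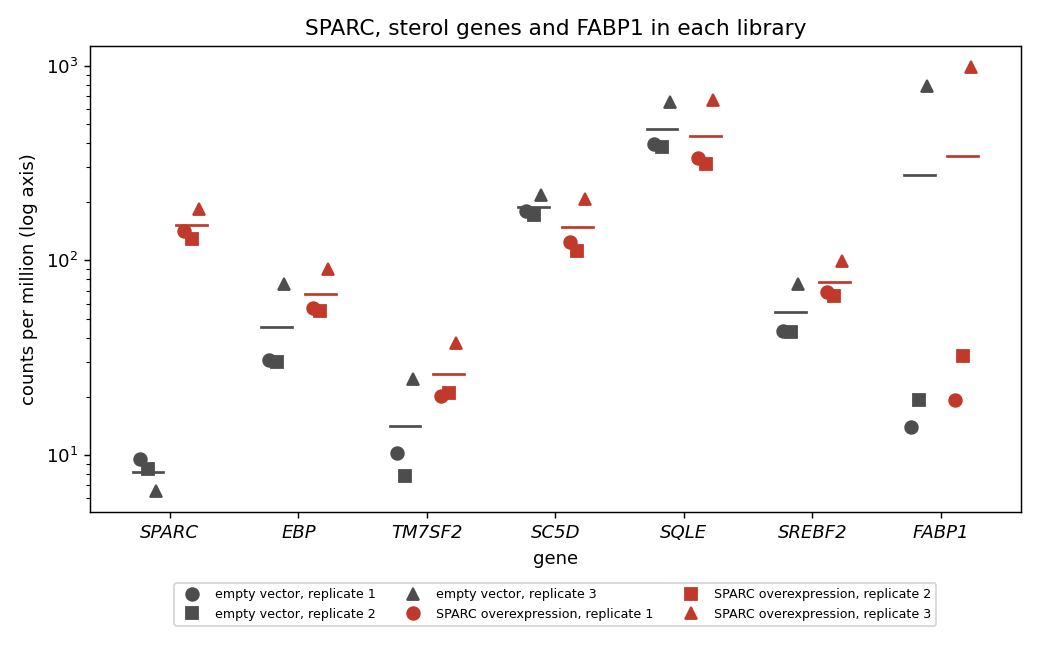
CPM on a log axis (y) of 7 genes (x) in each library, with a line at each group mean. SPARC is higher in the 3 overexpression libraries, and EBP, TM7SF2, SC5D, SQLE, SREBF2 and FABP1 are each highest in replicate 3 of both groups.

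Genes of cholesterol uptake and SREBP control included SCARB1, which rose. For cholesterol uptake and SREBP control, 18 of 18 were tested, 9 rising and 2 falling when paired (10 and 2 adjusted over the list alone) and 3 rising and 1 falling when corrected (9 and 1 adjusted over the list alone). The uptake list had camera adjusted p = 0.436 unpaired, 0.114 paired and 0.00706 (adjusted p = 0.665 with an estimated correlation) corrected, and 0.00149 to 0.914 over the preset-correlation fits. The uptake list had a median, mean and test of differing sign, with median and mean log2 changes of 0.19 and -0.02 corrected (camera up). SCARB1, the HDL receptor, rose in both (unpaired 0.76 ± 0.23, paired 0.81 ± 0.14, corrected 0.44 ± 0.07). LRP1 (unpaired 0.78 ± 0.20, paired 0.77 ± 0.17, corrected 0.20 ± 0.08) and SCAP (unpaired 0.91 ± 0.27, paired 0.98 ± 0.18, corrected 0.24 ± 0.08), the SREBP escort protein, rose in the paired fit. INSIG1, which retains SCAP in the endoplasmic reticulum, fell in both (unpaired -4.21 ± 1.41, paired -4.32 ± 0.75, corrected -4.19 ± 0.76), on 12, 17 and 157 counts with the vector and 0, 1 and 8 with SPARC. Its unpaired value was -2.15 without vector replicate 3, and its counts are uncertain because the counting is not described. SREBF2, which encodes a sterol-regulated transcription factor, rose in the paired fit as well (unpaired 0.52 ± 0.27, paired 0.55 ± 0.11, corrected 0.10 ± 0.08). For cholesterol efflux, LXR and esterification, 14 of 15 were tested, 3 rising and 0 falling when paired (7 and 0 adjusted over the list alone) and 1 rising and 0 falling when corrected (1 and 0 adjusted over the list alone). Unpaired, 1 higher and 0 lower passed adjusted over the list alone. The efflux list had camera adjusted p = 0.29 unpaired, 0.16 paired and 0.248 corrected, and 0.107 to 0.511 over the preset-correlation fits. PLTP, the phospholipid transfer protein, rose in both (unpaired 1.00 ± 0.24, paired 1.05 ± 0.20, corrected 0.45 ± 0.11), and RXRA in the paired fit alone (unpaired 0.74 ± 0.25, paired 0.78 ± 0.15, corrected -0.06 ± 0.10). SOAT2 (unpaired 0.75 ± 0.25, paired 0.76 ± 0.26, corrected 0.28 ± 0.22) and NR1H2 (unpaired 0.80 ± 0.39, paired 0.86 ± 0.31, corrected 0.04 ± 0.24) passed neither, and nor did ABCA1 (unpaired -0.19 ± 0.14, paired -0.19 ± 0.09, corrected 0.01 ± 0.07) and SOAT1 (unpaired -0.21 ± 0.17, paired -0.20 ± 0.10, corrected 0.19 ± 0.07). ABCG1 was too low to test, at 0.0183 CPM with the vector and 0 with SPARC.

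Components of PI3K-AKT-mTOR signalling went both ways in the paired fit. For PI3K-AKT-mTOR pathway components, 27 of 31 were tested, 9 rising and 5 falling when paired (9 and 9 adjusted over the list alone) and 0 rising and 1 falling when corrected (0 and 1 adjusted over the list alone). Unpaired, 4 higher and 3 lower passed adjusted over the list alone. The PI3K list had camera adjusted p = 0.887 unpaired, 0.949 paired and 0.875 corrected, and 0.691 to 0.995 over the preset-correlation fits. The PI3K list had a positive median and mean but a test directed down, with median and mean log2 changes of 0.051 and 0.047 corrected. The median over all genes tested in that fit was 0.056. The S6 kinase gene RPS6KB1 (unpaired -0.48 ± 0.12, paired -0.47 ± 0.10, corrected -0.03 ± 0.07) and PIK3C2A (unpaired -0.57 ± 0.15, paired -0.56 ± 0.10, corrected -0.08 ± 0.07) fell in the paired fit, and RPTOR (unpaired 0.62 ± 0.17, paired 0.63 ± 0.16, corrected 0.05 ± 0.08) and EIF4EBP1 (unpaired 0.98 ± 0.28, paired 0.95 ± 0.27, corrected -0.11 ± 0.11) rose. PIK3CA, a catalytic subunit gene of PI3K, fell (unpaired -0.44 ± 0.12, paired -0.44 ± 0.10, corrected 0.12 ± 0.09). AKT1 rose (unpaired 0.52 ± 0.17, paired 0.55 ± 0.15, corrected 0.05 ± 0.08), and PIK3R1 (unpaired -0.30 ± 0.11, paired -0.30 ± 0.10, corrected 0.07 ± 0.09) did not pass. None of these 7 genes passed with the correction, but PIK3CA passed as higher (0.24) in that fit without pair 3. For growth factor receptors and ligands feeding PI3K, 24 of 32 were tested, 4 rising and 1 falling when paired (4 and 1 adjusted over the list alone) and 4 rising and 2 falling when corrected (5 and 2 adjusted over the list alone). Unpaired, 2 higher and 1 lower passed adjusted over the list alone. The receptor and ligand list had camera adjusted p = 0.887 unpaired, 0.802 paired and 0.875 corrected, and 0.393 to 0.974 over the preset-correlation fits. The receptor and ligand list had a median, mean and test of differing sign, with median and mean log2 changes of 0.09 and -0.11 unpaired (camera up), 0.09 and -0.12 paired (camera up), 0.01 and -0.23 corrected (camera up). FGFR4 (unpaired 1.15 ± 0.24, paired 1.19 ± 0.22, corrected 0.35 ± 0.08) and IGF2 (unpaired 0.90 ± 0.28, paired 0.98 ± 0.19, corrected 0.35 ± 0.09) rose in both paired tests, and EREG, which encodes epiregulin, fell in both (unpaired -2.86 ± 0.52, paired -2.83 ± 0.61, corrected -2.33 ± 0.64). ERBB2 rose in the paired fit (unpaired 0.76 ± 0.19, paired 0.77 ± 0.17, corrected 0.22 ± 0.08). For FOXO target genes, 18 of 20 were tested, 3 rising and 1 falling when paired (3 and 1 adjusted over the list alone) and 2 rising and 1 falling when corrected (5 and 2 adjusted over the list alone). FOXO target genes had camera adjusted p = 0.684 unpaired, 0.837 paired and 0.919 corrected, and 0.0997 to 0.974 over the preset-correlation fits. FOXO target genes had a median, mean and test of differing sign, with median and mean log2 changes of -0.05 and 0.01 unpaired (camera down), 0.02 and -0.01 corrected (camera up). SESN1 fell (unpaired -0.44 ± 0.24, paired -0.41 ± 0.11, corrected -0.13 ± 0.07) and PINK1 rose (unpaired 0.70 ± 0.42, paired 0.79 ± 0.20, corrected 0.29 ± 0.13) in the paired fit. CDKN1B (unpaired -0.29 ± 0.11, paired -0.29 ± 0.09, corrected -0.19 ± 0.07) and CITED2 (unpaired -0.52 ± 0.33, paired -0.53 ± 0.36, corrected -0.45 ± 0.35) did not pass.

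Genes of bile acid, fatty acid and lipoprotein metabolism went both ways, with APOA2 rising and PDK4 falling in both paired tests. For bile acid synthesis and transport, 13 of 17 were tested, 3 rising and 0 falling when paired (3 and 0 adjusted over the list alone) and 1 rising and 0 falling when corrected (1 and 0 adjusted over the list alone). The bile acid list had camera adjusted p = 0.632 unpaired, 0.174 paired and 0.384 corrected, and 0.111 to 0.914 over the preset-correlation fits. CYP27A1 (unpaired 0.66 ± 0.27, paired 0.69 ± 0.10, corrected 0.07 ± 0.09) and HSD3B7 (unpaired 0.79 ± 0.42, paired 0.93 ± 0.19, corrected 0.22 ± 0.09) rose in the paired fit, while ABCB4 (unpaired -0.67 ± 0.23, paired -0.65 ± 0.22, corrected -0.41 ± 0.17) and AMACR (unpaired 1.31 ± 0.72, paired 1.39 ± 0.70, corrected 1.62 ± 0.68) did not pass. For fatty acid and triglyceride synthesis, 18 of 19 were tested, 5 rising and 1 falling when paired (6 and 1 adjusted over the list alone) and 3 rising and 0 falling when corrected (6 and 0 adjusted over the list alone). The lipogenic list had camera adjusted p = 0.562 unpaired, 0.174 paired and 0.0389 (adjusted p = 0.665 with an estimated correlation) corrected, and 0.0108 to 0.914 over the preset-correlation fits. FASN, the fatty acid synthase, rose in the paired fit (unpaired 1.00 ± 0.41, paired 1.16 ± 0.21, corrected 0.19 ± 0.07), with DGAT1 (unpaired 0.87 ± 0.34, paired 0.97 ± 0.24, corrected 0.16 ± 0.13), AGPAT2 (unpaired 1.04 ± 0.41, paired 1.05 ± 0.26, corrected 0.01 ± 0.26) and MLXIPL (unpaired 1.04 ± 0.43, paired 1.19 ± 0.23, corrected 0.37 ± 0.12). For fatty acid oxidation and PPARA targets, 16 of 20 were tested, 2 rising and 2 falling when paired (2 and 2 adjusted over the list alone) and 1 rising and 1 falling when corrected (1 and 1 adjusted over the list alone). Unpaired, 0 higher and 1 lower passed adjusted over the list alone. The oxidation list had camera adjusted p = 0.562 unpaired, 0.881 paired and 0.875 corrected, and 0.141 to 0.912 over the preset-correlation fits. The oxidation list had a median, mean and test of differing sign, with median and mean log2 changes of 0.01 and -0.16 corrected (camera down). PDK4, the pyruvate dehydrogenase kinase, fell in both (unpaired -3.60 ± 0.82, paired -3.24 ± 0.77, corrected -2.86 ± 0.67). ACADM fell (unpaired -0.38 ± 0.14, paired -0.37 ± 0.11, corrected -0.02 ± 0.07) and ACADVL rose (unpaired 0.40 ± 0.18, paired 0.42 ± 0.11, corrected -0.09 ± 0.06) in the paired fit, and ETFDH (unpaired -0.34 ± 0.21, paired -0.35 ± 0.14, corrected -0.10 ± 0.10) did not pass. For apolipoproteins and lipoprotein assembly, 15 of 15 were tested, 5 rising and 1 falling when paired (5 and 1 adjusted over the list alone) and 3 rising and 0 falling when corrected (4 and 2 adjusted over the list alone). The apolipoprotein list had camera adjusted p = 0.436 unpaired, 0.0547 paired and 0.402 corrected, and 0.0408 to 0.914 over the preset-correlation fits. APOA2 rose in both (unpaired 0.78 ± 0.20, paired 0.81 ± 0.13, corrected 0.47 ± 0.11). APOB fell (unpaired -0.25 ± 0.11, paired -0.25 ± 0.08, corrected 0.04 ± 0.08) and APOE rose (unpaired 0.74 ± 0.39, paired 0.83 ± 0.13, corrected -0.43 ± 0.13) in the paired fit, and APOC2 (unpaired 1.30 ± 0.56, paired 1.34 ± 0.59, corrected 0.69 ± 0.62) did not pass.

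Hepatocyte genes included ASGR1, which rose, and ALB, which fell. For hepatocyte secreted and differentiation genes, 23 of 23 were tested, 8 rising and 1 falling when paired (10 and 1 adjusted over the list alone) and 5 rising and 2 falling when corrected (9 and 3 adjusted over the list alone). The hepatocyte list had camera adjusted p = 0.29 unpaired, 0.0602 paired and 0.0138 (adjusted p = 0.665 with an estimated correlation) corrected, and 0.0029 to 0.946 over the preset-correlation fits. ASGR1, the asialoglycoprotein receptor subunit, rose in both (unpaired 1.02 ± 0.34, paired 1.11 ± 0.15, corrected 0.50 ± 0.07), and ASGR2 (unpaired 0.57 ± 0.17, paired 0.59 ± 0.12, corrected 0.11 ± 0.07) in the paired fit. CEBPA (unpaired 3.02 ± 0.95, paired 3.21 ± 1.04, corrected 2.26 ± 0.87) did not pass. ALB, the albumin gene, chosen after its values were seen, fell in both (unpaired -0.84 ± 0.37, paired -0.84 ± 0.09, corrected -0.51 ± 0.09), from 2728, 1620 and 3727 CPM to 1345, 986 and 2188 CPM in replicates 1 to 3. For cytochromes P450, conjugation and drug transport, 22 of 32 were tested, 3 rising and 1 falling when paired (3 and 1 adjusted over the list alone) and 3 rising and 1 falling when corrected (3 and 1 adjusted over the list alone). Unpaired, 0 higher and 1 lower passed adjusted over the list alone. The P450 list had camera adjusted p = 0.847 unpaired, 0.977 paired and 0.402 corrected, and 0.204 to 0.977 over the preset-correlation fits. The P450 list had a median, mean and test of differing sign, with median and mean log2 changes of -0.000531 and 0.01 unpaired (camera down), 0.03 and 0.03 paired (camera down). The efflux pump gene ABCB1 fell in both (unpaired -0.72 ± 0.15, paired -0.73 ± 0.12, corrected -0.45 ± 0.08) and UGT1A6 rose in both (unpaired 0.97 ± 0.38, paired 1.02 ± 0.18, corrected 1.25 ± 0.14). SULT1A1 rose in the paired fit (unpaired 0.51 ± 0.15, paired 0.52 ± 0.11, corrected -0.04 ± 0.07), and UGT2B4 (unpaired -1.58 ± 0.63, paired -1.45 ± 0.74, corrected -1.09 ± 0.72) did not pass. UGT1A genes share exons, so their counts are uncertain.

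Matrix genes went both ways, and SPARCL1, a paralog of SPARC, fell from a low level. For matricellular proteins and collagens, 28 of 33 were tested, 7 rising and 4 falling when paired (8 and 6 adjusted over the list alone) and 3 rising and 4 falling when corrected (5 and 6 adjusted over the list alone). Unpaired, 0 higher and 1 lower passed adjusted over the list alone. The matrix list had camera adjusted p = 0.436 unpaired, 0.724 paired and 0.0171 (adjusted p = 0.665 with an estimated correlation) corrected, and 0.000112 to 0.912 over the preset-correlation fits. SPARCL1 fell in both (unpaired -5.64 ± 1.05, paired -5.89 ± 0.65, corrected -5.62 ± 0.56), on 197, 43 and 224 counts with the vector and 1, 0 and 7 with SPARC. COL4A2, a basement membrane collagen, fell in both (unpaired -2.54 ± 0.66, paired -2.45 ± 0.63, corrected -3.16 ± 0.67). LAMA5 rose in the paired fit (unpaired 1.16 ± 0.29, paired 1.23 ± 0.28, corrected 0.19 ± 0.07), and HSPG2 (unpaired 0.96 ± 0.29, paired 0.91 ± 0.29, corrected 0.03 ± 0.09) did not pass. Summed CPM of the 12 stromal markers, 1 list of other cell types, was 63.9, 75.6 and 75.8 in vector replicates 1 to 3 and 44.5, 38.2 and 70.6 in overexpression replicates 1 to 3, and ACTA2 made up 69.9% of it. Without ACTA2 the sums were 22.2, 46.1 and 20.4 CPM with the vector and 1.76, 1.88 and 18.4 CPM with SPARC. For integrins and focal adhesion, 17 of 20 were tested, 7 rising and 2 falling when paired (8 and 3 adjusted over the list alone) and 0 rising and 0 falling when corrected (0 and 0 adjusted over the list alone). Unpaired, 3 higher and 0 lower passed adjusted over the list alone. The integrin list had camera adjusted p = 0.633 unpaired, 0.68 paired and 0.875 corrected, and 0.347 to 0.922 over the preset-correlation fits. The integrin list had a median, mean and test of differing sign, with median and mean log2 changes of 0.02 and -0.02 paired (camera up), 0.03 and -0.23 corrected (camera down). ZYX (unpaired 0.92 ± 0.21, paired 0.90 ± 0.17, corrected -0.05 ± 0.09), SRC (unpaired 0.69 ± 0.16, paired 0.70 ± 0.15, corrected 0.16 ± 0.09), BCAR1 (unpaired 1.03 ± 0.29, paired 1.11 ± 0.23, corrected 0.18 ± 0.11) and PXN (unpaired 0.53 ± 0.18, paired 0.52 ± 0.16, corrected 0.14 ± 0.09) rose in the paired fit and not with the correction.

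Of the epithelial and mesenchymal markers named, EPCAM alone passed both paired tests. For epithelial markers, 13 of 15 were tested, 2 rising and 2 falling when paired (2 and 2 adjusted over the list alone) and 0 rising and 2 falling when corrected (0 and 2 adjusted over the list alone). Epithelial markers had camera adjusted p = 0.847 unpaired, 0.977 paired and 0.0067 (adjusted p = 0.665 with an estimated correlation) corrected, and 0.00128 to 0.999 over the preset-correlation fits. Epithelial markers had a median, mean and test of differing sign, with median and mean log2 changes of 0.04 and 0.03 unpaired (camera down), 0.03 and -0.06 paired (camera down). EPCAM fell in both (unpaired -0.39 ± 0.13, paired -0.38 ± 0.10, corrected -0.29 ± 0.07) and KRT18 rose in the paired fit (unpaired 0.32 ± 0.22, paired 0.32 ± 0.09, corrected -0.12 ± 0.07). ESRP2 (unpaired 0.41 ± 0.19, paired 0.40 ± 0.18, corrected -0.15 ± 0.10) and TJP1 (unpaired -0.24 ± 0.12, paired -0.23 ± 0.10, corrected -0.02 ± 0.07) did not pass. Squamous epithelium markers without PERP summed to 304, 402 and 115 CPM with the vector and 6.52, 9.56 and 313 CPM with SPARC. For mesenchymal markers and EMT regulators, 16 of 21 were tested, 1 rising and 1 falling when paired (0 and 1 adjusted over the list alone) and 1 rising and 0 falling when corrected (1 and 2 adjusted over the list alone). The mesenchymal list had camera adjusted p = 0.684 unpaired, 0.68 paired and 0.371 corrected, and 0.111 to 0.912 over the preset-correlation fits. VIM fell in the paired fit (unpaired -4.08 ± 1.21, paired -4.96 ± 0.76, corrected -5.05 ± 1.16) and TIMP1 rose (unpaired 0.67 ± 0.22, paired 0.68 ± 0.21, corrected 0.16 ± 0.13). SNAI1 (unpaired 1.27 ± 0.56, paired 1.28 ± 0.63, corrected 0.74 ± 0.51) and ZEB1 (unpaired -0.23 ± 0.13, paired -0.22 ± 0.12, corrected 0.21 ± 0.09) did not pass. VIM is also expressed by stromal cells, whose summed CPM was lowest in overexpression replicates 1 and 2. For TGF-beta target genes, 17 of 20 were tested, 6 rising and 2 falling when paired (6 and 2 adjusted over the list alone) and 2 rising and 1 falling when corrected (3 and 2 adjusted over the list alone). TGF-beta target genes had camera adjusted p = 0.684 unpaired, 0.271 paired and 0.925 corrected, and 0.167 to 0.978 over the preset-correlation fits. BMP4 rose in both (unpaired 0.50 ± 0.15, paired 0.50 ± 0.09, corrected 0.25 ± 0.07), TGFB1 rose in the paired fit (unpaired 0.77 ± 0.22, paired 0.81 ± 0.19, corrected -0.03 ± 0.09) and TGFBR1 fell in it (unpaired -0.54 ± 0.13, paired -0.54 ± 0.11, corrected -0.12 ± 0.07), and SMAD6 (unpaired 0.77 ± 0.35, paired 0.72 ± 0.31, corrected 0.21 ± 0.23) did not pass. For WNT/beta-catenin target genes, 18 of 18 were tested, 5 rising and 1 falling when paired (5 and 1 adjusted over the list alone) and 2 rising and 0 falling when corrected (2 and 0 adjusted over the list alone). Unpaired, 2 higher and 0 lower passed adjusted over the list alone. The WNT list had camera adjusted p = 0.562 unpaired, 0.291 paired and 0.89 corrected, and 0.108 to 0.922 over the preset-correlation fits. The WNT list had a median, mean and test of differing sign, with median and mean log2 changes of 0.02 and -0.03 corrected (camera up). NOTUM, a secreted inhibitor of WNT proteins, rose in both (unpaired 1.30 ± 0.33, paired 1.41 ± 0.32, corrected 0.34 ± 0.09). SP5 (unpaired 0.99 ± 0.19, paired 1.00 ± 0.17, corrected -0.06 ± 0.08) and MYC (unpaired 0.35 ± 0.14, paired 0.36 ± 0.11, corrected 0.13 ± 0.07) rose in the paired fit and LGR5 fell (unpaired -0.31 ± 0.16, paired -0.31 ± 0.08, corrected -0.05 ± 0.07). STAB1, which encodes a scavenger receptor that binds SPARC, did not pass (unpaired -0.70 ± 0.67, paired -0.62 ± 0.71, corrected -1.35 ± 0.72).

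Immediate early and inflammatory genes had the smallest camera p-values with the correction, both directed down (adjusted p = 0.604 for each with an estimated correlation). For immediate early genes, 16 of 19 were tested, 2 rising and 3 falling when paired (3 and 3 adjusted over the list alone) and 0 rising and 6 falling when corrected (0 and 6 adjusted over the list alone). Unpaired, 0 higher and 3 lower passed adjusted over the list alone. Immediate early genes had camera adjusted p = 0.29 unpaired, 0.495 paired and 1.15e-05 (adjusted p = 0.604 with an estimated correlation) corrected, and 2.47e-10 to 0.495 over the preset-correlation fits. Immediate early genes had a median, mean and test of differing sign, with median and mean log2 changes of 0.01 and -0.70 unpaired (camera down). DUSP1, a MAP kinase phosphatase, fell from 17.0 ± 3.41 to 6.67 ± 0.831 CPM, and FOSB fell in both (unpaired -5.26 ± 1.03, paired -5.14 ± 0.91, corrected -5.57 ± 0.92). FOS did not pass (unpaired -3.72 ± 0.80, paired -3.81 ± 1.30, corrected -3.85 ± 1.47), at 31.1, 45.1 and 9.96 CPM with the vector and 0.895, 1.15 and 4.44 CPM with SPARC. The squamous marker KRT13 and the stromal marker DCN were, like FOS, lowest in overexpression replicates 1 and 2. IER2 rose in the paired fit (unpaired 0.61 ± 0.20, paired 0.62 ± 0.17, corrected -0.08 ± 0.14). For NF-kB and acute phase inflammation, 14 of 21 were tested, 2 rising and 4 falling when paired (2 and 5 adjusted over the list alone) and 0 rising and 3 falling when corrected (0 and 6 adjusted over the list alone). Unpaired, 0 higher and 1 lower passed adjusted over the list alone. The inflammation list had camera adjusted p = 0.402 unpaired, 0.0597 paired and 5.83e-05 (adjusted p = 0.604 with an estimated correlation) corrected, and 1.07e-07 to 0.912 over the preset-correlation fits. The chemokine genes CCL2 (unpaired -5.08 ± 1.91, paired -5.28 ± 0.66, corrected -5.21 ± 0.64) and CXCL2 (unpaired -1.65 ± 1.64, paired -2.07 ± 0.33, corrected -1.94 ± 0.28) fell in both. CCL2 had 13, 11 and 387 counts with the vector and 0, 0 and 11 with SPARC, and an unpaired value of -1.59 without vector replicate 3. In the libraries numbered 3, 11 of 14 tested members of this list were higher than in the others. IL8 fell in the paired fit (unpaired -1.92 ± 0.29, paired -1.86 ± 0.23, corrected -1.30 ± 0.42), from 22.9 ± 9.08 to 6.04 ± 0.564 CPM, and ORM1 rose in it (unpaired 0.45 ± 0.49, paired 0.50 ± 0.12, corrected 0.26 ± 0.10). Unpaired, CXCL2 ranged from -5.25 without overexpression replicate 3 to 1.08 without vector replicate 3, and ORM1 ranged from -0.061 without overexpression replicate 3 to 1.06 without vector replicate 3. For interferon response, 15 of 24 were tested, 1 rising and 1 falling when paired (0 and 0 adjusted over the list alone) and 0 rising and 0 falling when corrected (0 and 0 adjusted over the list alone). Interferon response had camera adjusted p = 0.684 unpaired, 0.805 paired and 0.247 corrected, and 0.146 to 0.995 over the preset-correlation fits. ISG15 rose in the paired fit (unpaired 1.20 ± 0.54, paired 1.45 ± 0.38, corrected 0.55 ± 0.27). IFI44 (unpaired -2.99 ± 1.15, paired -3.49 ± 1.19, corrected -3.16 ± 1.09) and OAS1 (unpaired 0.36 ± 0.20, paired 0.35 ± 0.19, corrected 0.42 ± 0.14) did not pass.

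MCM5 rose and MDM2 fell in both paired tests, in the lists of cell cycle genes and p53 targets. For cell cycle and proliferation, 28 of 28 were tested, 5 rising and 3 falling when paired (5 and 3 adjusted over the list alone) and 1 rising and 1 falling when corrected (1 and 1 adjusted over the list alone). The cell cycle list had camera adjusted p = 0.915 unpaired, 0.918 paired and 0.875 corrected, and 0.0647 to 0.995 over the preset-correlation fits. The cell cycle list had a median, mean and test of differing sign, with median and mean log2 changes of -0.05 and 0.01 unpaired (camera down), -0.06 and 0.02 paired (camera down), 0.04 and 0.02 corrected (camera down). MCM5, a subunit of the replicative helicase, rose in both (unpaired 0.84 ± 0.20, paired 0.82 ± 0.18, corrected 0.45 ± 0.12). MCM2 (unpaired 0.58 ± 0.23, paired 0.54 ± 0.14, corrected 0.08 ± 0.07) and MCM7 (unpaired 0.51 ± 0.21, paired 0.47 ± 0.12, corrected 0.05 ± 0.07) rose in the paired fit, and CCNE2 (unpaired -0.50 ± 0.22, paired -0.46 ± 0.18, corrected 0.04 ± 0.11) did not pass. For p53 target genes, 18 of 18 were tested, 5 rising and 5 falling when paired (5 and 5 adjusted over the list alone) and 0 rising and 2 falling when corrected (1 and 5 adjusted over the list alone). p53 target genes had camera adjusted p = 0.847 unpaired, 0.805 paired and 0.000344 (adjusted p = 0.665 with an estimated correlation) corrected, and 1.46e-05 to 0.974 over the preset-correlation fits. p53 target genes had a median, mean and test of differing sign, with median and mean log2 changes of -0.17 and 0.02 unpaired (camera down), -0.19 and 0.05 paired (camera down). MDM2, the ubiquitin ligase of p53, fell in both (unpaired -0.65 ± 0.19, paired -0.64 ± 0.12, corrected -0.30 ± 0.07). TP53INP1 fell (unpaired -0.67 ± 0.22, paired -0.66 ± 0.15, corrected -0.26 ± 0.09) and BAX (unpaired 0.84 ± 0.20, paired 0.83 ± 0.18, corrected 0.26 ± 0.09) and FDXR (unpaired 0.79 ± 0.27, paired 0.73 ± 0.19, corrected -0.19 ± 0.07) rose in the paired fit. For unfolded protein response and ER chaperones, 21 of 21 were tested, 6 rising and 2 falling when paired (6 and 5 adjusted over the list alone) and 2 rising and 0 falling when corrected (2 and 0 adjusted over the list alone). The ER chaperone list had camera adjusted p = 0.887 unpaired, 0.987 paired and 0.248 corrected, and 0.233 to 0.999 over the preset-correlation fits. The ER chaperone list had a median, mean and test of differing sign, with median and mean log2 changes of -0.05 and 0.05 unpaired (camera down), -0.04 and 0.06 paired (camera down). HYOU1 rose in both (unpaired 0.54 ± 0.18, paired 0.57 ± 0.13, corrected 0.29 ± 0.08). SDF2L1 (unpaired 0.79 ± 0.26, paired 0.83 ± 0.23, corrected -0.23 ± 0.14) and CALR (unpaired 0.36 ± 0.13, paired 0.35 ± 0.08, corrected 0.11 ± 0.07) rose and SEL1L fell (unpaired -0.31 ± 0.11, paired -0.31 ± 0.09, corrected 0.09 ± 0.07) in the paired fit. For integrated stress response (ATF4 targets), 18 of 19 were tested, 5 rising and 2 falling when paired (7 and 2 adjusted over the list alone) and 1 rising and 1 falling when corrected (1 and 1 adjusted over the list alone). The ATF4 list had camera adjusted p = 0.83 unpaired, 0.724 paired and 0.0974 corrected, and 0.0647 to 0.978 over the preset-correlation fits. SHMT2 rose in both (unpaired 0.68 ± 0.17, paired 0.66 ± 0.15, corrected 0.36 ± 0.09). SLC7A5 (unpaired 0.63 ± 0.19, paired 0.61 ± 0.14, corrected -0.05 ± 0.06) and TRIB3 (unpaired 0.50 ± 0.19, paired 0.52 ± 0.11, corrected -0.14 ± 0.08) rose in the paired fit, and VLDLR (unpaired -1.35 ± 0.50, paired -1.42 ± 0.57, corrected -1.11 ± 0.58) did not pass. For NRF2 targets and iron or ferroptosis genes, 21 of 21 were tested, 5 rising and 3 falling when paired (7 and 4 adjusted over the list alone) and 2 rising and 0 falling when corrected (7 and 2 adjusted over the list alone). The NRF2 list had camera adjusted p = 0.887 unpaired, 0.896 paired and 0.402 corrected, and 0.00766 to 0.999 over the preset-correlation fits. The NRF2 list had a median, mean and test of differing sign, with median and mean log2 changes of -0.01 and 0.10 unpaired (camera up). FTL (unpaired 0.59 ± 0.22, paired 0.64 ± 0.12, corrected 0.21 ± 0.08) rose and GCLM (unpaired -0.76 ± 0.24, paired -0.71 ± 0.15, corrected -0.23 ± 0.08) and GCLC (unpaired -0.44 ± 0.16, paired -0.43 ± 0.10, corrected -0.18 ± 0.07) fell in the paired fit.

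Ribosomal protein genes formed the list that camera called in each of the 3 fits. For ribosomal proteins, 28 of 28 were tested, 13 rising and 0 falling when paired (13 and 0 adjusted over the list alone) and 7 rising and 1 falling when corrected (15 and 1 adjusted over the list alone). Unpaired, 12 higher and 0 lower passed adjusted over the list alone. Ribosomal proteins had camera adjusted p = 0.000824 (adjusted p = 0.957 with an estimated correlation) unpaired, 2.33e-05 (adjusted p = 0.83 with an estimated correlation) paired and 0.000361 (adjusted p = 0.665 with an estimated correlation) corrected, and 1.93e-07 to 0.00428 over the preset-correlation fits. RPS2 (unpaired 0.88 ± 0.21, paired 0.92 ± 0.16, corrected 0.08 ± 0.07), RPLP1 (unpaired 0.71 ± 0.18, paired 0.73 ± 0.13, corrected 0.77 ± 0.18) and RPLP2 (unpaired 0.64 ± 0.16, paired 0.66 ± 0.13, corrected -0.05 ± 0.07) rose in the paired fit. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. For glycolysis and hypoxia, 22 of 22 were tested, 8 rising and 0 falling when paired (8 and 0 adjusted over the list alone) and 2 rising and 0 falling when corrected (4 and 1 adjusted over the list alone). Glycolysis and hypoxia had camera adjusted p = 0.202 unpaired, 0.0146 (adjusted p = 0.83 with an estimated correlation) paired and 0.875 corrected, and 0.0142 to 0.994 over the preset-correlation fits. GPI rose in both (unpaired 0.49 ± 0.14, paired 0.50 ± 0.10, corrected 0.34 ± 0.07), and GAPDH (unpaired 0.53 ± 0.13, paired 0.54 ± 0.10, corrected -0.01 ± 0.07), ALDOA (unpaired 0.65 ± 0.17, paired 0.67 ± 0.11, corrected -0.02 ± 0.07) and TPI1 (unpaired 0.50 ± 0.15, paired 0.51 ± 0.11, corrected 0.05 ± 0.07) in the paired fit. For mitochondrially encoded genes, 6 of 13 were tested, 0 rising and 0 falling when paired (0 and 0 adjusted over the list alone) and 0 rising and 0 falling when corrected (1 and 0 adjusted over the list alone). The mitochondrial list had camera adjusted p = 0.887 unpaired, 0.949 paired and 0.399 corrected, and 0.369 to 0.994 over the preset-correlation fits. The mitochondrial list had a median, mean and test of differing sign, with median and mean log2 changes of -0.02 and 0.05 unpaired (camera down), -0.03 and 0.05 paired (camera down). MT-CO3 (unpaired 0.18 ± 0.12, paired 0.19 ± 0.07, corrected 0.25 ± 0.08), MT-ND5 (unpaired -0.14 ± 0.12, paired -0.14 ± 0.08, corrected 0.04 ± 0.07) and MT-ND2 (unpaired -0.09 ± 0.12, paired -0.10 ± 0.09, corrected 0.12 ± 0.08) did not pass. MT-CO1 held 3 to 18 counts per library (unpaired 0.40 ± 0.75, paired 0.42 ± 0.84, corrected 0.52 ± 0.89), and its counts are uncertain for the reason given for INSIG1. For replication-dependent histones, 9 of 17 were tested, 0 rising and 0 falling when paired (0 and 0 adjusted over the list alone) and 0 rising and 0 falling when corrected (0 and 1 adjusted over the list alone). The histone list had camera adjusted p = 0.887 unpaired, 0.949 paired and 0.402 corrected, and 0.367 to 0.974 over the preset-correlation fits. HIST1H1C (unpaired -0.39 ± 0.30, paired -0.42 ± 0.30, corrected -0.93 ± 0.28), HIST1H2BO (unpaired 0.91 ± 0.82, paired 0.63 ± 0.67), HIST1H3H (unpaired 0.79 ± 0.83, paired 1.10 ± 0.91) and HIST1H4C (unpaired 0.22 ± 0.34, paired 0.27 ± 0.27, corrected 0.19 ± 0.23) did not pass.

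Some markers of other tissues were lowest in overexpression replicates 1 and 2. KRT13, a keratin of squamous epithelium, was at 75.2, 76.7 and 17.4 CPM in vector replicates 1 to 3 and at 1.28, 1.12 and 40.7 CPM in overexpression replicates 1 to 3. DCN, a stromal proteoglycan, was at 5.44, 5.83 and 10.3 CPM and at 0.0959, 0.0607 and 4.20 CPM. For fibroblast and stellate markers, 7 of 12 were tested, 0 rising and 0 falling when paired (0 and 0 adjusted over the list alone) and 0 rising and 0 falling when corrected (0 and 0 adjusted over the list alone). The stromal list had camera adjusted p = 0.0971 unpaired, 0.16 paired and 0.00706 (adjusted p = 0.665 with an estimated correlation) corrected, and 1.40e-13 to 0.334 over the preset-correlation fits. RGS5 (unpaired -1.28 ± 0.56, paired -1.51 ± 0.55, corrected -0.99 ± 0.41), LUM (unpaired -2.06 ± 1.19, paired -3.39 ± 1.38, corrected -2.76 ± 1.72), DCN (unpaired -2.29 ± 1.32, paired -3.85 ± 1.19, corrected -3.26 ± 1.41) and COL3A1 (unpaired -2.28 ± 1.38, paired -3.50 ± 2.73, corrected -3.44 ± 3.07) did not pass. For endothelial markers, 4 of 10 were tested, 1 rising and 1 falling when paired (1 and 1 adjusted over the list alone) and 0 rising and 0 falling when corrected (0 and 1 adjusted over the list alone). Unpaired, 0 higher and 1 lower passed adjusted over the list alone. It was too short for a set test. ERG fell (unpaired -2.75 ± 0.77, paired -2.79 ± 0.83, corrected -2.65 ± 0.93) and ENG rose (unpaired 0.81 ± 0.43, paired 0.96 ± 0.22, corrected 0.15 ± 0.11) in the paired fit, and KDR (unpaired -1.20 ± 0.78, paired -1.22 ± 0.75, corrected -1.10 ± 0.82) and VWF (unpaired 0.07 ± 1.04, paired -0.54 ± 0.61, corrected -1.0 ± 0.60) did not pass. For leukocyte markers, 4 of 11 were tested, 0 rising and 1 falling when paired (0 and 1 adjusted over the list alone) and 0 rising and 1 falling when corrected (0 and 1 adjusted over the list alone). It was too short for a set test. PTPRC, which encodes CD45, fell in both (unpaired -2.94 ± 1.12, paired -3.50 ± 0.99, corrected -3.10 ± 0.88). LYZ (unpaired 0.07 ± 0.72, paired 0.19 ± 0.11, corrected 0.47 ± 0.23) and HBA1 (unpaired 0.01 ± 0.69, paired 0.31 ± 0.68, corrected -0.71 ± 0.72) did not pass. For human embryonic kidney packaging-line markers, 3 of 10 were tested, 0 rising and 1 falling when paired (0 and 1 adjusted over the list alone) and 0 rising and 0 falling when corrected (0 and 0 adjusted over the list alone). It was too short for a set test. LIN28B fell in the paired fit (unpaired -0.36 ± 0.32, paired -0.35 ± 0.09, corrected 0.10 ± 0.08), and PAX8 (unpaired 0.51 ± 0.74, paired 0.52 ± 0.39, corrected 0.14 ± 0.39) did not pass.

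**Figure D3:**
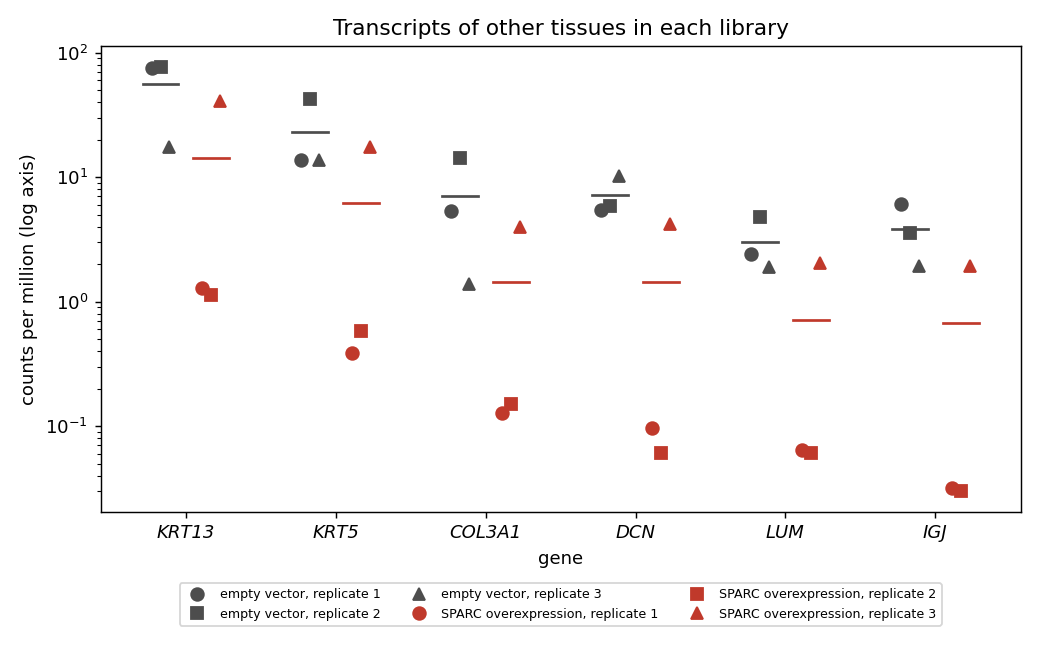
CPM on a log axis (y) of 6 genes of squamous epithelium, stroma or plasma cells (x) in each library, with a line at each group mean. KRT13 lies at 1.28 and 1.12 CPM in overexpression replicates 1 and 2 and at 17.4 CPM or more in the other 4 libraries.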

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

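The tests with the GC and length correction, DESeq2 with the block, number 3 against 1 and 2, both libraries numbered 3 or a pair left out, and thinning were chosen after the data were examined. SPARC kept its direction and stayed past the threshold in 20 alternatives, with log2 fold changes of 3.89 to 4.48 and adjusted p (edgeR or DESeq2) of 7.46e-177 to 0.047. With 1 library left out it ranged from 4.05 to 4.33. RLE scaling, no filter, the stricter filter and the correction without the block each left 1 gene, SPARC, and the correction without the block gave 6 lists. The replicate block gave 3451 genes (650 at least 2-fold) and 2 lists. DESeq2 gave 1329 (284), and 4408 (744) with the block. Number 3 against 1 and 2 as a block gave 4375 (757) and 3 lists. The block after thinning gave 3455 (644) and 4 lists. Leaving out both libraries numbered 3 gave 6708 (1654) and 2 lists. The block with the GC and length correction gave 932 genes (101 at least 2-fold) and 10 lists. Leaving pair 1 out of that fit gave 55 (27) and 11 lists. Leaving pair 2 out gave 404 (100) and 10 lists. Leaving pair 3 out gave 3192 (455) and 8 lists. With 1 library left out the counts ran from 1 to 4333 genes, 1 to 1311 at least 2-fold and 1 to 3 lists, and the 4333 genes came without vector replicate 3. Leaving out overexpression replicate 3 gave 2 genes. These list counts are at the preset correlation, and with an estimated correlation camera called 0 lists in each of the 19 alternatives with set tests (adjusted p of 0.304 or more), with 5 at an unadjusted p under 0.05 over all of them. Fry called NF-kB and acute phase inflammation with the block and the correction (adjusted p = 0.0467), interferon response in that fit without pair 2 (adjusted p = 0.00937), and 0 lists in the other alternatives. With SPARC left out before scaling edgeR called 0 genes, with 3095 at an unadjusted p under 0.05, and DESeq2 called 1328. Unpaired, camera with an estimated correlation and fry called 0 lists, with 0 and 2 at an unadjusted p under 0.05, and camera at its preset correlation called 1. The cause was not tested for any of these changes, apart from the removal of the only gene called. Pseudocount alternatives do not apply to counts.

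The replicate block brought 113 named genes past the threshold, 73 higher and 40 lower, turned VWF in sign, and changed no other call among the named genes. Of the lists, it added glycolysis and hypoxia (adjusted p = 0.0146, and adjusted p = 0.830 with an estimated correlation) and changed no other call. Values that changed sign follow, as log2 fold changes for genes and camera adjusted p for lists, and the cause was not tested. With the block and the correction, the log2 fold change turned at ABCA1 0.0069, SOAT1 0.19, PIK3CA 0.12, PIK3R1 0.074, SC5D 0.021, RXRA -0.060, ACADVL -0.090, APOB 0.043, APOE -0.43, EIF4EBP1 -0.11, ZYX -0.048, ESRP2 -0.15. Also turned were KRT18 -0.12, ZEB1 0.21, TGFB1 -0.028, SP5 -0.057, SULT1A1 -0.042, CCNE2 0.044, FDXR -0.19, SDF2L1 -0.23, SEL1L 0.094, SLC7A5 -0.049, TRIB3 -0.14, GAPDH -0.013. In addition it turned at ALDOA -0.022, IER2 -0.084, RPLP2 -0.049, MT-ND5 0.039, MT-ND2 0.12, VWF -1.0, HBA1 -0.71, LIN28B 0.10. In the same fit the camera direction turned at PI3K-AKT-mTOR pathway components, FOXO target genes, integrins and focal adhesion and cytochromes P450, conjugation and drug transport (adjusted p = 0.875, 0.919, 0.875 and 0.402). Lists that turned as well were unfolded protein response and ER chaperones, integrated stress response (ATF4 targets), mitochondrially encoded genes and replication-dependent histones (adjusted p = 0.248, 0.0974, 0.399 and 0.402). With the correction and no block, the log2 fold change turned at SQLE 0.015, ABCA1 0.0055, SOAT1 0.19, PIK3CA 0.12, PIK3R1 0.066, SC5D 0.028, RXRA -0.070, ACADVL -0.091, APOB 0.040, APOE -0.41, EIF4EBP1 -0.056, ZYX -0.054. Further genes that turned there were ESRP2 -0.14, KRT18 -0.14, ZEB1 0.21, TGFB1 -0.022, SP5 -0.069, SULT1A1 -0.044, CCNE2 0.038, FDXR -0.18, SDF2L1 -0.24, SEL1L 0.090, SLC7A5 -0.050, TRIB3 -0.14. Genes that also turned in it were GAPDH -0.016, ALDOA -0.023, IER2 -0.10, RPLP2 -0.049, MT-ND5 0.040, MT-ND2 0.12, VWF -0.32, HBA1 -1.15, LIN28B 0.14. In the same fit the camera direction turned at growth factor receptors and ligands feeding PI3K, integrins and focal adhesion, TGF-beta target genes and WNT/beta-catenin target genes (adjusted p = 0.657, 0.602, 0.657 and 0.827). Other lists that turned were cytochromes P450, conjugation and drug transport (adjusted p = 0.827), unfolded protein response and ER chaperones (adjusted p = 0.62), integrated stress response (ATF4 targets) (adjusted p = 0.124), mitochondrially encoded genes (adjusted p = 0.54). Other lists that turned were replication-dependent histones (adjusted p = 0.377). With the block and the correction but without pair 1, the log2 fold change turned at SQLE 0.015, SOAT1 0.14, AKT1 -0.0068, PIK3CA 0.064, SC5D 0.033, RXRA -0.096, AGPAT2 -0.085, ACADM 0.017, ACADVL -0.088, APOE -0.36, RPTOR -0.021, EIF4EBP1 -0.17. Also turned were HSPG2 -0.045, ZYX -0.066, ESRP2 -0.18, KRT18 -0.074, ZEB1 0.20, TGFB1 -0.13, SMAD6 -0.083, SP5 -0.13, SULT1A1 -0.0066, MCM2 -0.00021, MCM7 -0.0076, CCNE2 0.012. In addition it turned at FDXR -0.21, SDF2L1 -0.25, SEL1L 0.075, SLC7A5 -0.029, TRIB3 -0.16, GAPDH -0.012, ALDOA -0.041, IER2 -0.019, RPLP2 -0.086, MT-ND5 0.015, MT-ND2 0.014, VWF -0.35. The remaining ones were LIN28B 0.025. In the same fit the camera direction turned at PI3K-AKT-mTOR pathway components, FOXO target genes, integrins and focal adhesion and TGF-beta target genes (adjusted p = 0.831, 0.403, 0.605 and 0.741). Lists that turned as well were WNT/beta-catenin target genes (adjusted p = 0.836), cytochromes P450, conjugation and drug transport (adjusted p = 0.63), unfolded protein response and ER chaperones (adjusted p = 0.358), integrated stress response (ATF4 targets) (adjusted p = 0.115). Lists that turned as well were NRF2 targets and iron or ferroptosis genes, glycolysis and hypoxia, mitochondrially encoded genes and replication-dependent histones (adjusted p = 0.836, 0.805, 0.481 and 0.367). With the block and the correction but without pair 2, the log2 fold change turned at SQLE 0.031, ABCA1 0.045, SOAT1 0.20, PIK3CA 0.090, PIK3R1 0.052, PMVK -0.0026, SC5D 0.047, NR1H2 -0.073, ACADVL -0.062, APOB 0.083, APOE -0.32, EIF4EBP1 -0.19. Further genes that turned there were HSPG2 -0.063, ESRP2 -0.17, TJP1 0.038, KRT18 -0.077, ZEB1 0.20, SULT1A1 -0.022, CCNE2 0.14, FDXR -0.21, SDF2L1 -0.19, SEL1L 0.064, SLC7A5 -0.056, TRIB3 -0.050. Genes that also turned in it were IER2 -0.025, RPLP2 -0.0014, MT-ND5 0.091, MT-ND2 0.16, VWF -0.89, HBA1 -0.47, LIN28B 0.082. In the same fit the camera direction turned at PI3K-AKT-mTOR pathway components (adjusted p = 0.922), FOXO target genes (adjusted p = 0.898), cytochromes P450, conjugation and drug transport (adjusted p = 0.204), unfolded protein response and ER chaperones (adjusted p = 0.402). Other lists that turned were integrated stress response (ATF4 targets), mitochondrially encoded genes and replication-dependent histones (adjusted p = 0.149, 0.369 and 0.485). With the block and the correction but without pair 3, the log2 fold change turned at SOAT1 0.24, PIK3CA 0.24, PIK3R1 0.20, PMVK -0.13, RXRA -0.15, CYP27A1 -0.054, AGPAT2 -0.31, ACADVL -0.11, APOB 0.054, APOE -0.64, RPS6KB1 0.042, ZYX -0.10. Also turned were ESRP2 -0.099, KRT18 -0.18, ZEB1 0.26, TGFB1 -0.0062, SP5 -0.099, LGR5 0.010, SULT1A1 -0.082, FDXR -0.17, SDF2L1 -0.26, SEL1L 0.16, SLC7A5 -0.063, TRIB3 -0.23. In addition it turned at GAPDH -0.044, ALDOA -0.069, IER2 -0.23, RPLP2 -0.046, MT-ND5 0.029, MT-ND2 0.20, VWF -1.85, HBA1 -1.59, LIN28B 0.22, PAX8 -0.071. In the same fit the camera direction turned at integrins and focal adhesion (adjusted p = 0.613), cytochromes P450, conjugation and drug transport (adjusted p = 0.563), cell cycle and proliferation (adjusted p = 0.588), unfolded protein response and ER chaperones (adjusted p = 0.233). Lists that turned as well were integrated stress response (ATF4 targets), mitochondrially encoded genes and replication-dependent histones (adjusted p = 0.413, 0.459 and 0.459). Other turns were HBA1 -0.024 with RLE size factors in place of TMM, HBA1 -0.024, growth factor receptors and ligands feeding PI3K (adjusted p = 0.931), cytochromes P450, conjugation and drug transport (adjusted p = 0.931), cell cycle and proliferation (adjusted p = 0.931) with no filter on low counts, matricellular proteins and collagens (adjusted p = 0.631), NRF2 targets and iron or ferroptosis genes (adjusted p = 0.942) with counts of at least 50 in 3 samples, VWF -0.54 with replicate block, VWF -0.61 with DESeq2 Wald test with the replicate block, VWF -0.56 with number 3 against 1 and 2 as a block, VWF -1.24, HBA1 -0.50, matricellular proteins and collagens (adjusted p = 0.82), cell cycle and proliferation (adjusted p = 0.82), p53 target genes (adjusted p = 0.92), unfolded protein response and ER chaperones (adjusted p = 0.92), replication-dependent histones (adjusted p = 0.928) with both libraries numbered 3 left out, VWF -0.41 with replicate block after thinning to the smallest library. With 1 library left out, the log2 fold changes of the genes that turned ranged over SQLE -0.55 to 0.17, CXCL2 -5.25 to 1.08, ORM1 -0.061 to 1.06, MT-CO1 -0.14 to 0.70, VWF -2.05 to 0.90, LYZ -0.73 to 1.13, HBA1 -0.39 to 0.96, PAX8 -0.17 to 1.06. The camera adjusted p of the lists that turned ranged over cholesterol synthesis 0.14 to 0.93, growth factor receptors and ligands feeding PI3K 0.691 to 0.974, epithelial markers 0.557 to 0.974, cell cycle and proliferation 0.0647 to 0.757, integrated stress response (ATF4 targets) 0.0647 to 0.978, mitochondrially encoded genes 0.738 to 0.994. For other lists that turned it ranged over bile acid synthesis and transport 0.146 to 0.914, FOXO target genes 0.0997 to 0.974, TGF-beta target genes 0.321 to 0.978, p53 target genes 0.478 to 0.974, interferon response 0.146 to 0.912, replication-dependent histones 0.523 to 0.974. For the last lists it ranged over PI3K-AKT-mTOR pathway components 0.691 to 0.93, matricellular proteins and collagens 0.0647 to 0.912, cytochromes P450, conjugation and drug transport 0.414 to 0.913, unfolded protein response and ER chaperones 0.738 to 0.978, NRF2 targets and iron or ferroptosis genes 0.691 to 0.999. Of the genes that turned, 8 were past the threshold in the new direction, in the corrected fit without pair 3: SOAT1, PIK3CA, APOE, KRT18, ZEB1, SEL1L, TRIB3, LIN28B.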

Other observations

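The tests of replicate 3, of KEGG pathways, of GC content within a group, of squamous, fibroblast, endothelial and leukocyte markers and of other-tissue RNA in replicate 3 were chosen after the results had been seen.

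Libraries numbered 3 stood apart from those numbered 1 and 2 in both groups. With the group held constant, 2539 genes differed between number 3 and the mean of 1 and 2 (edgeR, adjusted p under 0.05), 1153 higher and 1386 lower in number 3. FABP1, the liver fatty acid binding protein, was at 789 and 983 CPM in the 2 libraries numbered 3 and between 13.9 and 32.2 CPM in the other 4. The acute phase and iron-binding gene LCN2 had a log2 difference of 7.14 ± 0.26, IGFBP1 3.39 ± 0.09, HP 4.10 ± 0.14 and C3 2.35 ± 0.09. The glucose transporter gene SLC2A1 was lower by a log2 difference of -2.94 ± 0.14, and ASNS, the asparagine synthetase, by -2.35 ± 0.11. Of the NF-kB and acute phase list, 11 of 14 tested members were higher and 0 lower. Of the cholesterol synthesis list, 17 of 20 were higher and 0 lower, with 0.89 ± 0.10 for SQLE, and of the cell cycle list 1 was higher and 20 of 28 were lower. Camera gave adjusted p = 3.19e-34, 4.05e-20 and 2.56e-12 for these 3 lists, and adjusted p = 0.143, 0.143 and 0.202 with an estimated correlation.

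In the paired and corrected comparison of the groups, 15 of 226 KEGG pathways passed camera at its preset correlation. Oxidative phosphorylation led, with 23 of 103 members higher and 1 lower (adjusted p = 7.19e-05, and adjusted p = 0.0740 paired without the correction). The ribosome had 25 of 124 higher and 4 lower (adjusted p = 0.000209, and 0.000234 without the correction). Pentose and glucuronate interconversions had 7 of 21 higher and 0 lower (adjusted p = 0.000510, and 0.885), and TNF signalling 2 of 63 higher and 9 lower (adjusted p = 0.00603, and 0.357). Without the correction 2 pathways passed, 1 of them among the 15. With an estimated correlation 0 passed (adjusted p = 0.993 for each of these 4), with 2 at an unadjusted p under 0.05, and with fry 0 and 30.

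The paired group difference followed GC content. Thinning each library to the smallest total left 100.1% as many paired calls, so unequal depth did not account for their number. Thinning keeps each gene's expected share of its library, so it cannot show whether the GC trend arose with depth. A trend of the same kind was present within the vector group, where the log2 ratio of replicate 3 to replicates 1 and 2 had a Spearman rho of 0.614 with GC content over genes, but little of it within the overexpression group, where rho was 0.0626. Of the paired calls, 14.1% were kept after the correction, so a GC-dependent yield of the libraries may account for many of them. A change of GC-rich and GC-poor genes caused by SPARC stays open, because 2 of 3 vector libraries carry the opposite trend to the overexpression libraries.

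Many squamous and some stromal transcripts were lower in overexpression replicates 1 and 2 than in the other 4 libraries. Of the squamous markers not seen before, 24 of 30, or 80%, had this order. Chance gives 6.67%, but the order came from these data, and markers may move together. RNA from another tissue may be the source. The same order held for 41.7% of the fibroblast markers, between the bounds set for the test. It held for 9.09% of the leukocyte markers, 2 of which were at 1 CPM or more in both low libraries. Neither decides. The haemoglobin genes HBB and HBA2 had 1421 and 83 counts in vector replicate 1 and at most 12 and 2 elsewhere. Blood RNA there was not tested. Loss under SPARC overexpression stays open, since the highest overexpression library stood at 1.52 times the lowest vector library for summed squamous CPM (2.72 times without PERP, 60.8% of the sum) and at 1.10 times for fibroblast CPM, and that rests on overexpression replicate 3 alone. Without ACTA2 the highest fibroblast sum under overexpression was 18.4 CPM and the lowest with the vector 20.4 CPM.

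A GC trend was not the whole separation of libraries numbered 3. After the GC and length correction 3926 genes differed among the 3 numbers (271% of the 1449 without it). Between number 3 and the others 4493 did, against 2539. Such counts rise as spread falls, so the GC share is open. Squamous RNA did not account for a separation that both groups share, since summed squamous CPM moved in opposite directions. The log2 ratios of replicate 3 to replicates 1 and 2 were -0.81 with the vector and 1.43 with SPARC. Their product was -1.16 (-1.62, 5.28 and -8.55 without PERP). Non-liver RNA does not account for a rise of hepatocyte genes. Their median log2 difference was 0.78 (quartiles 0.49 and 0.94), with 13 of 23 higher and 1 lower. That rise could hide a small share of such RNA. Both libraries numbered 3 exceeded the other 4 at 2 each of 11 leukocyte, 8 endothelial, 12 fibroblast and 40 squamous markers, too few to decide. A difference in culture or harvest that the numbers share was not tested, because the labels name none.

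The 6 libraries make 10 splits into groups of 3, and 4 of them part the same pairs, too few for a share under 0.05. The real split called 1 gene without the block and 3451 genes with it (edgeR), and the highest of the other splits called 0 in both cases.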
